A study of Morus alba with 2 samples.

How the data were processed

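Degradome libraries were made from young leaves of greenhouse-grown mulberry (Morus alba), 1 from untreated plants and 1 from plants under drought. Degradome sequencing records RNA molecules with a free monophosphate at the 5′ end, which include the downstream fragments left by miRNA-guided cleavage as well as other decay products. Per the labels' protocols, each group held 3 plants, drought samples were taken at 5, 10 and 15 days, RNA of the time points of a treatment was mixed in equal amounts, and about 200 µg of total RNA entered poly(A) selection. The series design text names only the 15-day point, so the share of each time point in the drought library rests on the protocol. The libraries were amplified for 5 and then 20 PCR cycles without molecular identifiers, per the labels' protocols, so reads are not independent molecules and every interval and floor below covers counting error only.

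The authors deposited, for each library, a table of distinct tags with the read count of each tag and the place of each match on a transcript model, a table of positions with a peak category from 0 to 4, which is a score, and a table of miRNA-target pairs. The matching program, its mismatch limit and the category definitions are not given in the sources used here. The tags were 47 nt long in both libraries, whereas the file trailer states a mapped read size of 21 and the protocol describes MmeI digestion, which gives short tags; this difference was not resolved. The position tables equalled the tag counts summed at each position in 100% of positions of both libraries. The deposited pair table carries an alignment score, a category score, a p-value rounded by the authors and a column whose header names a depth-scaled tag number. The pair tables of both libraries were the same file. Its values in that column equalled the raw control read count at the site in 71 of 72 pairs and its categories equalled the control categories in 72, so the table was read as a list of sites selected in the control library and the drought copy was not used as a measurement. Such a selection lowers drought/control ratios at the listed positions.

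All lengths given for transcript models, 17675 in the control and 17458 in the drought table, were multiples of 3. The first 3 bases were covered in 1197 models and read ATG in each, and 3692185 codons read in frame held 0 stop codons before the last codon. The models therefore hold coding sequence, and sites in untranslated regions were not analysed here. Positions are counted from 1 at the first base of the coding sequence. No genome or annotation was used, so chromosome positions are not given, and the files do not pair the transcript identifiers with gene names. At most 2 identifiers that were higher and 2 that were lower are printed.

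Library size was the number of reads with at least 1 sense match, each read counted once, which was 2040655 in control and 3250912 in drought. A transcript's or site's reads counted each match in full. The floor of 3 counts corresponded to 1.47 RPM (reads scaled to library size) in control and 0.923 in drought. Ratios were given with the exact conditional binomial (Clopper-Pearson) 95% interval. With 1 library per condition there is no replicate check, and no p-value between conditions was computed. The interval compares these 2 libraries, not the conditions.

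Conserved sites were also searched for directly, because many listed positions lay 1 nt from the main pile of tags. Sequences of 27 conserved miRNA families of the Arabidopsis type, written from memory, were aligned to the transcript bases seen in tags. A mismatch cost 1 and a G:U pair 0.5, with a factor of 2 at miRNA nucleotides 2 to 13, and sites with a penalty up to 5 were kept. A site was called supported when the highest position within 3 nt of the base opposite nucleotide 10 held at least 10 reads over both libraries and was the highest position of its transcript in at least 1 library. This search was settled after a first version had been seen. That version asked for every base of a site to be covered and gave 21 supported sites and no miR166 site. The cost of 0.35 for an uncovered base opposite nucleotide 10 or later, the 3 nt window and the support rule were then chosen with those results in view, and a cost of 0.4, which gave 24 sites, would also have left miR166 out. The presence of miR166 among the supported sites is therefore not independent evidence. Each of 20 sets of shuffled miRNA sequences was searched with the same final rule.

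Gene lists had been planned by product name, and since the files give no names that comparison was not run as planned. In its place, transcripts were translated from their tags and grouped by 39 short peptide motifs. A transcript joined a family only where tags of either library covered its motif. Members with an uncovered motif are therefore missed, families may be incomplete, and membership depends on the tags being compared. A first set of motifs was run and its ratios were seen before the set was final. Several motifs were then tightened or dropped for specificity, and others (xyloglucan endotransglucosylase, pectinesterase, cellulose synthase, ascorbate peroxidase, superoxide dismutase, thioredoxin, Aux/IAA and SnRK2) were added before their ratios were seen. The set is thus not independent of these data. The final motifs matched 376 times in the translated sequences and 2 times in the same sequences reversed. The reversed matches were 1 for expansin, against 6 forward, and 1 for tubulin, against 12 forward. Reversed sequences do not test whether a match belongs to the named family. The planned lists for ribosomal proteins and for proline and osmolytes had no motif and were not analysed here. For families with at least 3 transcripts of at least 50 reads, the median log2 ratio, with 0.5 added to each count, was placed among 10000 random lists of the same size matched on mean reads in 20 bins. This percentile describes these 2 libraries.

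Peak categories were rebuilt for a drought library thinned to the control's read total. Of 5 definitions tried, the one that matched the deposited categories best was kept; it matched 99.95% of control positions and 99.7% of drought positions. The rule for named items was fixed before the data were examined. It took the 15 pairs with most tags at the site in each library, the 10 transcripts with the largest and the 10 with the smallest ratio among those with at least 100 reads, the 5 with most reads in each library, and the 3 with most reads in each list; where identifiers could not be printed, values are given without them. Sites from the search and further family members are named outside that rule and were chosen after their values were seen.

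Alternatives covered scaling by a median-of-ratios size factor or without the 10 transcripts with most tags, tags within 1 nt, single-match tags, tags divided by their matches, count minimums of 20 and 200, distinct positions, removal of the highest position, and thinning. The number of distinct positions is bounded by transcript length. Alternatives for the site search and the motif families were chosen after seeing the data. In libraries simulated with Poisson counting error alone, at the depths of the control and drought comparison, 95.4% of intervals over 11543 transcripts held the true fold. Of 50 transcripts lowered to 0.5-fold, 41 had an interval off 1, and of 50 raised 2-fold, 50 had. Copies made by PCR were not simulated, so these values check the calculation and not how the intervals perform in the real libraries. All 270 planted miRNA sites were found at the planted base, but each was a full complement with every base covered and a clear peak. Mismatches, uncovered bases and competing peaks of similar height were not simulated. This result therefore does not measure how many real sites the search finds. The random-list procedure placed 6.33% of 300 unshifted lists outside its middle 95%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, Biopython 1.88 and matplotlib 3.10.9 were used.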

Results

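The study compared which transcripts miRNAs cleave in leaves of well-watered and drought-stressed mulberry. 1 control and 1 drought degradome library were available. The control library held 2842343 reads matched to transcript models and the drought library 4281944, of which 2040655 and 3250912 matched the sense strand. Sense tags fell on 17676 transcripts in control and 17459 in drought. The drought library had more reads but fewer distinct sense tags, 862437 against 923550, or 3.77 reads per distinct tag against 2.21. There were no biological replicates, so each ratio below carries a counting interval only and has no replicate check.

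The first comparison asked how cleavage signal at the miRNA targets listed in the authors' deposited table differed between the libraries. The miR408 site showed the lowest ratio among sites with at least 10 control reads, with 132 reads in control and 21 in drought, 10.0-fold lower (95% interval 6.29 to 16.7). The 3 miR166 sites, a family that targets class III HD-ZIP transcription factors, together had 249 and 151 reads, 2.63-fold lower (2.14 to 3.24). The miR319 site, of a family that targets TCP transcription factors, had 101 and 183 reads, and its ratio of 1.14 had an interval that held 1 (0.887 to 1.46). The miR156 site, of a family that targets SPL transcription factors, had 62 and 52 reads, 1.90-fold lower (1.29 to 2.80), but tags within 1 nt gave the opposite direction, 364 and 670 reads with a ratio of 1.16 (1.02 to 1.32). One miRn99-3p site present in 2 transcript models had 10 and 45 reads, a ratio of 2.82 (1.40 to 6.29).

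The table listed 72 pairs at 66 distinct sites in 63 transcripts. Every pair had a control read at its site, and 26 had a drought read. Of the 72 pairs, 34 rested on 1 control read, and 23 of these had no drought read. The 16 miR396b pairs each had 1 control read, and 4 of them had a drought read. Among the 39 pairs of miRNAs named miRn in the table, 12 had a drought read and 2 had at least 10 control reads. A pair without a drought read was not detectable in drought at this depth, since 0 reads allow up to 0.923 RPM (reads scaled to the library size). Sites of miR162 and miRn74 with 4 control reads, and of miR166f and miRn99-3p with 5, had 0 drought reads. By that floor they were at least 2.12-fold and 2.66-fold lower, respectively. Within 1 nt the miR162 site went the other way, with 8 and 17 reads. Summed over the 66 sites, 661 control and 584 drought reads were 1.80-fold lower in drought (1.61 to 2.02), at positions that had been selected in the control library. The 30 sites of conserved families gave 577 and 433 reads, 2.12-fold lower (1.87 to 2.41).

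Several listed positions held few tags beside a large pile at the next base. At the miR396b site at base 353, 1 control and 9 drought reads lay at the listed base, and 655 and 1145 at the next. At the miR171a site at base 1283 the listed base had 2 and 6 reads and the next 298 and 641. Among 15 distinct sites with at least 10 control reads at the listed or the next base, the next base held more in 12. A search with conserved miRNA sequences was therefore made, with settings chosen after the data were seen. It gave 26 supported sites in 12 of 27 families, 17 of them away from any listed site, against a mean of 0.35 supported sites per shuffled set and at most 2. The miR396b site at base 353 was not among them, so its large pile is absent from the sums and interval counts below. The only supported miR396 site had 0 control and 14 drought reads, a ratio of at least 2.08 by its interval.

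**Figure D1:**
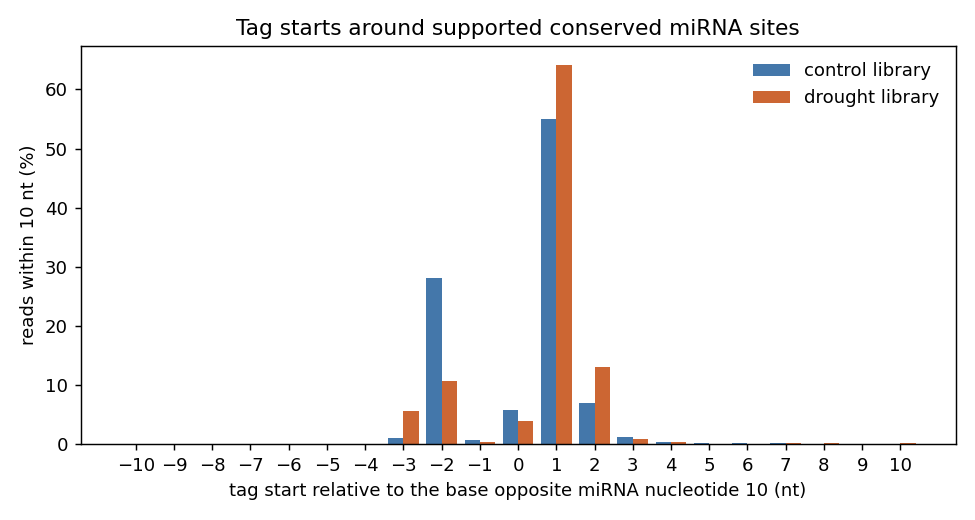
Bars show the percentage of reads within 10 nt (y axis) whose tag starts at each offset in nt from the base opposite miRNA nucleotide 10 (x axis), for the control and the drought library over the 26 supported sites. The offset of 1 nt downstream holds 55.0% of control and 64.1% of drought reads.

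At these sites the families moved in different directions. Reads at a site also follow the tag total of its transcript, so these ratios and those at listed sites do not isolate cleavage. The miR408 site at base 17 held 48.5% of its transcript's control reads and 46.3% of its drought reads. The miR393 site at base 1514 held 49.6% and 48.8%, and the miR164 site at base 653 held 85.4% and 74.7%. Shares rose at others, such as 40.9% and 60.9% at the miR156 site at base 1172. They fell at the miR166 sites, from 22.1% to 11.8% at base 560 and from 21.4% to 15.0% at base 590. At the miR171 site at base 1254 the share fell from 58.2% to 42.8%. The miR393 sites, of a family that targets the TIR1/AFB auxin receptors, had 467 control and 1249 drought reads, a ratio of 1.68 (1.51 to 1.87). The site with more of them, GAAACAATGCGATCCCTTTGGA with tags from base 1514, had 393 and 1105 reads. The 2 miR164 sites, of a family that targets NAC transcription factors, had 117 and 524 reads, a ratio of 2.81 (2.30 to 3.47); the larger was CCAACGTGCCCTGCTTCTCCA with tags from base 653, and 1 of the 2 transcripts carries the NAC motif. The miR172 site CTGCAGCATCATCAGGATTCT, of a family that targets AP2 transcription factors, had 121 and 244 reads, a ratio of 1.27 (1.01 to 1.59). The miR167 site had 73 and 161 reads, a ratio of 1.38 (1.04 to 1.85), and the 4 miR160 sites, of a family that targets auxin response factors, had 618 and 1158, a ratio of 1.18 (1.07 to 1.30).

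The miR408 site GCCAGGGAAGAGTCAGTGCAA was lowest again, with 196 and 31 reads from base 17, 10.1-fold lower (6.87 to 15.2). The 2 miR171 sites share the sequence GATATTGGCGCGGCTCAATCA, the textbook target of miR171 in GRAS transcription factors, and differed. Tags from base 1254 of one transcript had 1265 and 457 reads, 4.41-fold lower. This base lies 2 nt upstream of the predicted base and 1 nt downstream of the listed miR171d position. Tags 1 nt downstream of the predicted base had 680 and 457, 2.37-fold lower. Tags from base 1284 of the other had 298 and 641, a ratio of 1.35 (1.18 to 1.55). Over both sites the log2 ratio of -1.18 became -0.50 at exactly 1 nt downstream. The 2 miR166 sites had 244 and 151 reads, 2.57-fold lower (2.09 to 3.17). The miR319 sites, with 388 and 616 reads, had a ratio of 0.997 (0.876 to 1.13), and the 5 miR858 sites, all with tags from base 301, had 187 and 249 reads and a ratio of 0.836 (0.689 to 1.02); exactly 1 nt downstream, where 9 reads lay, the log2 ratio was -0.99 (-3.33 to 1.22). For miR156, the site in the listed transcript had 288 and 608 reads, a ratio of 1.33 (1.15 to 1.53), a second had 8 and 69, a ratio of 5.41 (2.60 to 13.04), and another had 1 and 431 reads at a base 3 nt upstream of the predicted one. The tags of the last also fitted another transcript model, and 0 of them matched 1 place; the family's log2 ratio of 1.23 was 0.52 with single-match tags and 0.59 at exactly 1 nt downstream.

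**Figure D2:**
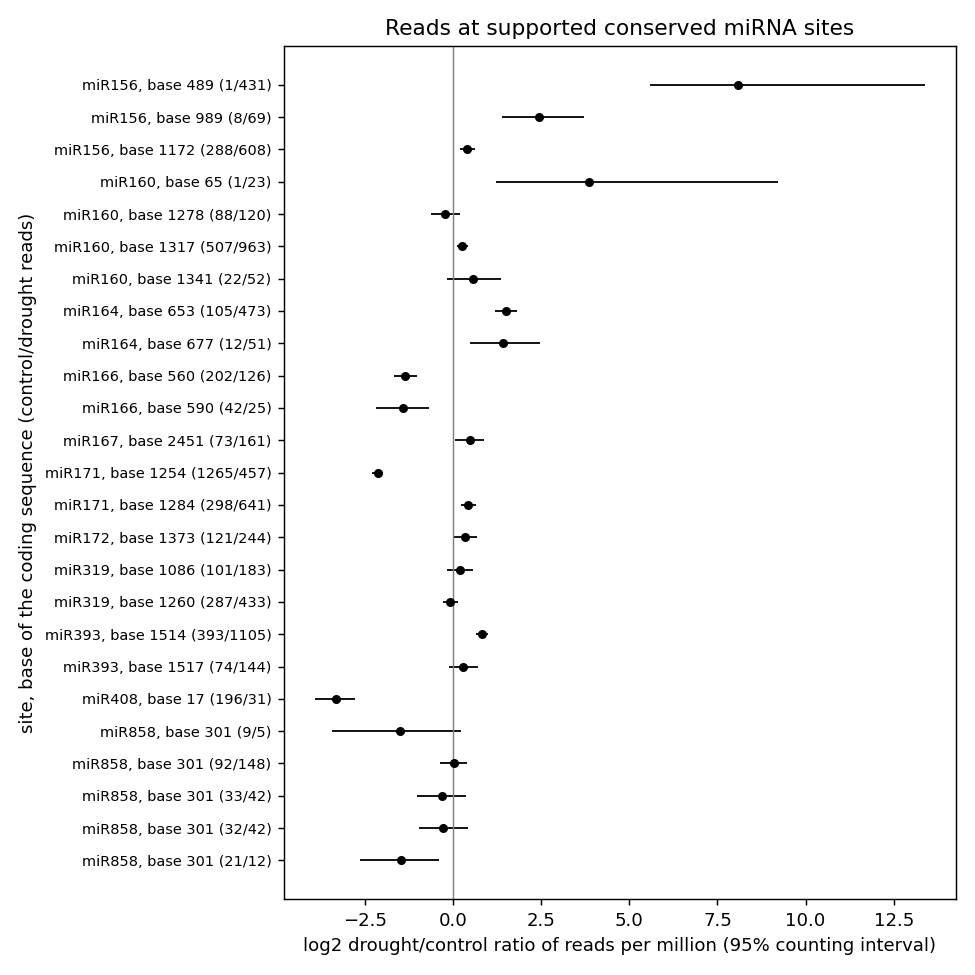
Points show the log2 drought/control ratio of RPM (x axis) at each supported site with reads in both libraries (y axis, with control and drought reads in brackets), and bars the 95% counting interval. Of all 26 sites, 12 have an interval above a ratio of 1, 5 below it and 9 across it.

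Summed over the 26 sites, 4271 control and 6603 drought reads gave a ratio of 0.970 (0.934 to 1.01). The total was lower over all positions within 3 nt, with a log2 ratio of -0.17 (-0.22 to -0.12), and with single-match tags, at -0.14 (-0.20 to -0.088). Without the site with most reads, the miR171 site at base 1254, 3006 and 6146 reads gave a ratio of 1.28 (1.23 to 1.34). Of the sites, 16 had more RPM in drought and 10 fewer, and the median log2 ratio of the 25 with reads in both libraries was 0.25. The intervals of 12 sites lay above 1, those of 5 below, and those of 9 held 1. All 26 sites were highest in their transcript in drought, the deeper library, and 22 were in control; 3 of the 12 had at most 1 control read. Such a selection can raise drought/control ratios. At the 22 sites, 8 intervals lay above 1, 5 below and 9 across it, and the summed ratio was 0.868 (0.834 to 0.905).

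Cleavage categories rank a position within its transcript, with category 0 the single highest position and category 4 a position of 1 read. Category 4 made up 58.2% of control positions (58.1 to 58.3) and 36.6% of drought positions (36.5 to 36.7), and category 2 made up 37.2% and 55.5%. Category 0 made up 1.04% and 1.39%, but 7.40% and 5.83% among positions with at least 5 reads, the opposite direction. With drought thinned to the control's read total, category 4 made up 46.3% and category 2 47.9%. Among transcripts with a single highest position of at least 10 reads in both libraries, 773 of 1524, or 50.7% (48.2 to 53.3), had it at the same base, against 1.23% for a randomly drawn drought position. This share depended on the read minimum and was 27.3% from 5 reads and 79.9% from 50.

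Transcript tag totals were compared because degradome tags follow both the level and the decay of an RNA. A transcript carrying the dehydrin K-segment, a motif of proteins that accumulate in dehydrating plant tissue, had 243 control and 59077 drought reads, 153-fold higher (135 to 174), at 60 and 94 distinct positions. Only 1 of the transcripts examined carried this motif in bases that tags covered. The largest ratios among transcripts with at least 100 reads were those of XM_010103626.1, with 1 and 483 reads and a ratio of 303 (54.2 to 12000), and XM_010100439.1, with 3 and 1399 reads and a ratio of 293 (99.96 to 1421). The smallest were those of XM_010100208.1, with 129 and 4 reads, and XM_010095405.1, with 120 and 4 reads, which were 51.4-fold and 47.8-fold lower. By distinct positions in place of reads, the log2 ratios of the higher pair went from 8.24 to 6.93 and from 8.19 to 4.18, and those of the lower pair from -5.68 to -4.36 and from -5.58 to -3.95. The files do not pair these identifiers with gene names. Transcripts with most reads included 3 carrying the chlorophyll a/b-binding motif in control. In 2 of these, 2250 of 20214 and 1768 of 19732 control reads matched 1 place, and the others were shared tags counted in full. The transcript with most in both libraries had 27154 and 121502 reads, 2.81-fold higher.

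Over 11543 transcripts with at least 50 reads, Spearman's rho between the libraries was 0.757 (bootstrap 95% interval 0.747 to 0.767) and Pearson's r of log2 values 0.738, across transcripts, which are not independent replicates. Of these, 1342 were over 2-fold higher and 1814 over 2-fold lower in drought, 27.3% together. The higher and lower counts were closer with the size factor, 1494 and 1647, and with a minimum of 200 reads, 686 and 712. By distinct positions the share was 16.8%. The median log2 ratio was -0.07.

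Of 12 transcripts with the motif of tubulin, the subunit of microtubules, 11 had an interval below 1, with a median 2.56-fold lower that lay under all random lists; its log2 ratio of -1.36 was -0.74 by distinct positions. Of these, 2 held the same tags; counted once, 10 of 11 lay below, with a median 2.32-fold lower at percentile 0.07. In the cell wall list, all 4 cellulose synthase and all 4 pectinesterase transcripts had intervals below 1, with medians 2.27-fold and 2.31-fold lower at percentiles 1.10 and 1.97. Cellulose synthase lay inside the middle 95% with a minimum of 20 reads, and pectinesterase with single-match tags, without the highest position and by distinct positions, where its median log2 ratio went from -1.21 to -0.46. Of 5 expansin transcripts, proteins that loosen cell walls, 4 had an interval below 1, and the one with 127 and 28 reads was 7.23-fold lower; the family's percentile was 0.03. The 3 xyloglucan endotransglucosylase transcripts had a median at percentile 46.9, inside the middle 95%.

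Some histone families lay low among random lists. Of 5 histone H3 transcripts, 3 were 9.31-fold to 10.02-fold lower, whereas the one with most reads had 2061 and 3609, a ratio of 1.10 (1.04 to 1.16); the family's median log2 ratio of -3.21 was -1.81 by distinct positions. Of 7 histone H2A transcripts, 5 had an interval below 1, with a family median 4.61-fold lower. This log2 ratio of -2.20 was -1.45 with single-match tags, and it was -0.37 by distinct positions and -0.15 with a minimum of 200 reads, both inside the middle 95%. All 4 H2B and all 5 H4 transcripts had intervals below 1, with percentiles of 5.03 and 3.34, inside the middle 95%. Both families lay below it with single-match tags, whereas by distinct positions their median log2 ratios went from -0.88 to -0.25 and from -0.89 to -0.22.

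Among photosynthesis families, 6 of 8 transcripts with the chlorophyll a/b-binding motif, carried by light-harvesting proteins, had an interval below 1 and 2 above, with a median 2.05-fold lower at percentile 1.12, and inside the middle 95% with a minimum of 200 reads. By distinct positions in place of reads the median turned to a log2 ratio of 0.35. A median of 44.4% of their bases in control and 42.5% in drought held a tag, and up to 89.0% and 83.3%; whether this bears on the turn was not tested. The Rubisco small subunit transcript had 16776 and 20235 reads, 1.32-fold lower.

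In the abscisic acid list, 11 of 19 transcripts with the PP2C motif, a phosphatase family with members that act in abscisic acid signalling, had an interval above 1 and 3 below, and the median ratio of 1.33 lay at percentile 98.6, and inside the middle 95% with a minimum of 200 reads. The most raised had 5 and 451 reads, a ratio of 56.6 (24.1 to 175), and another 74 and 1024, a ratio of 8.69 (6.86 to 11.2). The 6 SnRK2 transcripts had a median at percentile 78.0. Of 30 cytochrome P450 transcripts, 14 had an interval above 1 and 5 below, at percentile 99.7.

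Heat shock families were mixed. Of 7 HSP70 transcripts, 3 had an interval above 1 and 4 below; those with 29 and 700 reads and with 73 and 1246 reads had ratios of 15.2 and 10.7, and the one with most reads was 1.81-fold lower. The small HSP median lay at percentile 94.5, DnaJ at 9.40 and the single HSP90 transcript was 1.40-fold lower. The medians of aquaporin, thioredoxin, Aux/IAA and ubiquitin-conjugating E2 families lay at percentiles 39.3, 90.9, 35.3 and 93.8. In the antioxidant list the ascorbate peroxidase transcript was 1.77-fold lower and the 2 superoxide dismutase transcripts had ratios on both sides of 1. The catalase motif matched 0 transcripts in the bases that tags covered. No transcript with the NBS-LRR motif of the defence list reached 50 reads. The 2 ubiquitin transcripts had a median 1.32-fold lower.

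In all, 11 of 29 families with at least 3 transcripts lay outside the middle 95% of random lists, 9 low and 2 high, where the nominal level gives 1.45. Chance can give more, since 6.33% of simulated unshifted lists lay outside and random lists do not model tags shared between members. Under every alternative tried, tubulin, expansin and histone H3 lay low and cytochrome P450 high, and each of the other 7 families lay inside the middle 95% under at least 1 alternative. Bootstrap intervals of the median log2 ratio held 0 for histone H3 (-3.31 to 0.164) and cytochrome P450 (-0.0253 to 0.904). Those of tubulin (-1.96 to -0.641) and expansin (-2.83 to -0.107) did not. The motif set had been revised after ratios of a first set were seen, so the count of 11 families is not independent of the data.

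**Figure D3:**
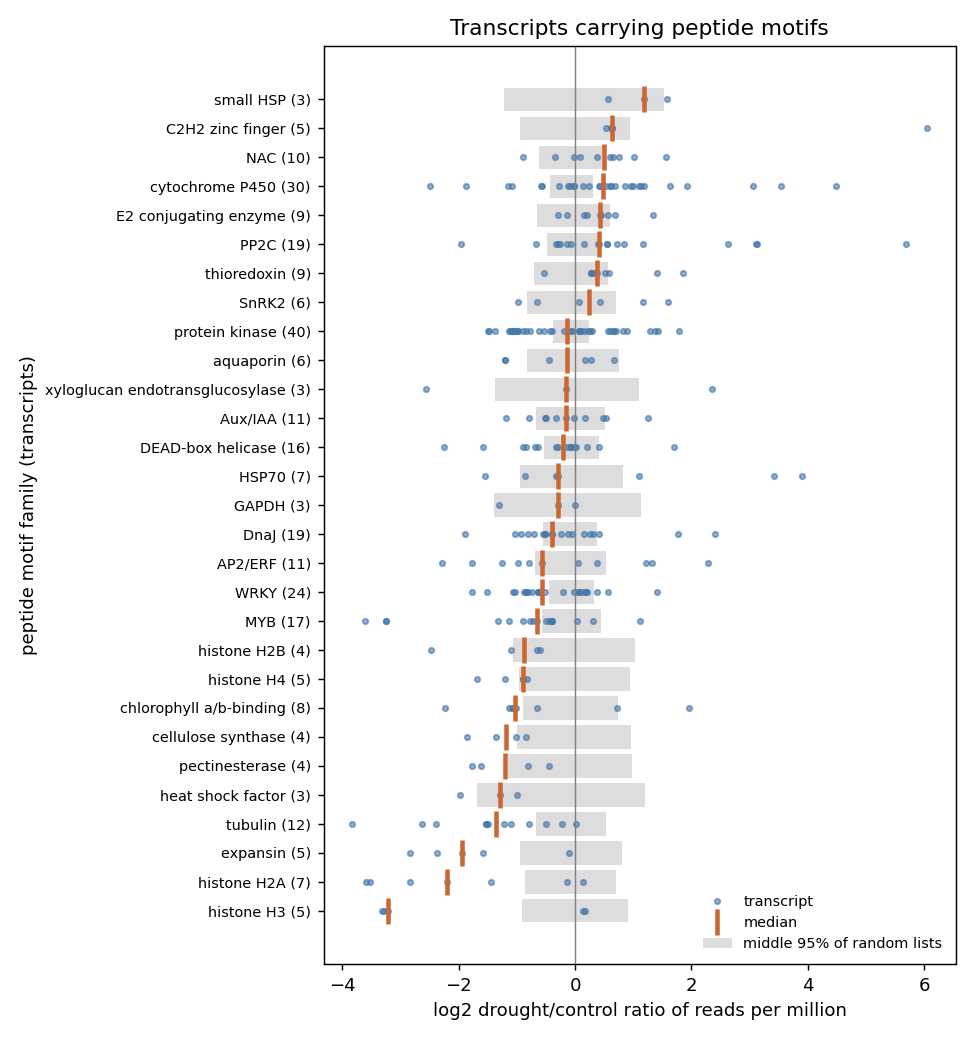
Points show the log2 drought/control ratio of RPM (x axis) of each transcript in the 29 motif families with at least 3 transcripts (y axis), coloured marks the family median and grey bars the middle 95% of random lists. Tubulin, expansin and the histone H2A and H3 families have medians left of the grey bars, and PP2C and cytochrome P450 right of them.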

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

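The test of ribosomal sequence was chosen only after the pile-up had been seen. Reads on the strand opposite to the transcript models were not used in the comparisons. Outside the 2 transcripts with most of them, they made up 2.16% of matched reads in drought (2.15 to 2.18) and 1.71% in control (1.70 to 1.73), a signal in unused data above the level in the control.

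Those 2 transcripts held most antisense reads. One had 736327 in control and 926383 in drought, 25.9% and 21.6% of all matched reads, and 99.7% and 99.5% of its antisense reads started within 5 neighbouring bases. The other had 21796 and 19878. A candidate explanation is ribosomal RNA sequence on the strand opposite to the gene model, tested by alignment to bacterial-type large-subunit rRNA written from memory. The smaller pile scored 36 points above the highest of 1000 shuffles, over 162 aligned bases at 77.2% identity, but the larger only 1 point above, over 30 aligned bases. For the larger pile, which holds most of the reads, the source stays open, and no biological explanation was tested.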

How the results depend on the processing

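Settings for the site search and the motif families were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because each condition had 1 library. The gene list comparison by product name was not run, for want of names. Of 484 alternative values, 435 stayed within the main interval or within 1.5 times the main count. Among alternatives of the headline results, such as sums, categories and library-wide shares, 36 stayed, 34 moved and 2 reversed. The other 399 that stayed belong to single sites, families and transcripts, some with wide intervals. The listed miR4376 site counted as staying although its log2 ratio went from 1.65 to -0.67 within 1 nt. The cause of the changes below was not tested.

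The log2 ratio summed over listed sites was -0.85, and it was -0.54 within 1 nt and -1.10 with single-match tags; for conserved families -1.09 became -0.60 within 1 nt. The miR156 listed site reversed within 1 nt, to 0.21. Pairs with at least 10 reads numbered 9 of the 26 in drought and 7 of the 72 in control, where 31 were of categories 0 to 2. At searched sites -0.04 became 0.0225 with the size factor, 0.0223 without the 10 transcripts with most tags, 0.0520 at exactly 1 nt downstream, -0.17 (-0.22 to -0.12) over all positions within 3 nt and -0.14 (-0.20 to -0.088) with single-match tags, the last 2 with intervals below 0; it became 0.36 (0.30 to 0.42) without the site with most reads, and -0.20 (-0.26 to -0.14) at the 22 sites highest in control, which are those highest in both libraries. Requiring every base covered gave 21 sites, a cost of 0.4 gave 24 and a penalty limit of 4 gave 18, against 26.

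Category differences (drought minus control, percentage points) for categories 0 to 4 became 0.55, -0.29, 10.7, 0.88 and -11.8 after drought was thinned to the control's read total; positions with a tag still differed, 738406 against 957877. With positions of at least 5 reads, categories 0 to 3 differed by -1.57, -0.45, 2.88 and -0.87, so that categories 0 and 3 reversed from 0.35 and 3.59; this minimum empties category 4 by definition, so its difference of 0 tests nothing, and it does not test depth. Same-position peaks were 27.3% from 5 reads, 79.9% from 50 and 55.7% within 1 nt. Spearman's rho was 0.812 and 0.602 with minimums of 20 and 200 reads, 0.727 by distinct positions and 0.745 without the highest position, and the share over 2-fold 30.2%, 24.0%, 16.8% and 28.3%. The drought/control depth ratio of 1.59 was 0.934 in distinct sequences.

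Low motif families numbered between 6 and 9, and high ones 2 or 3, in every alternative. The chlorophyll a/b-binding median turned to 0.35 by distinct positions, a count that transcript length bounds. A median of 44.4% of the family's bases in control and 42.5% in drought held a tag, and whether this bears on the turn was not tested. The turn is in positions and not in reads, whose median log2 ratio was -1.04. Of the 9 low families, 6 remained low with a minimum of 200 reads, 6 with single-match tags, where histone H2B and H4 were low too, and 6 by distinct positions, and 8 or 9 otherwise; PP2C was not high with the minimum of 200.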

Other observations

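The tests of a 1 nt shift and of other miRNA forms were chosen only after the offsets had been seen; those of shuffled sequences, pile-up and shared reads were set before their results. Of the transcription factor families outside the planned lists, MYB and WRKY lay outside the middle 95% of random lists, and both lay inside it with single-match tags, as MYB did with a minimum of 200 reads. The MYB median was 1.56-fold lower at percentile 1.47, with 10 of 17 transcripts below a ratio of 1 by their interval and 1 above; with transcripts that held the same tags counted once, 9 of 15 lay below, at percentile 1.89. The WRKY median was 1.48-fold lower at percentile 0.45, with 13 of 24 below and 3 above. The other 4 families lay inside it. The NAC median ratio of 1.41 lay at percentile 96.7, with 5 of 10 above and 2 below, and each of 5 C2H2 zinc finger transcripts had an interval above 1, at percentile 91.5. The heat shock factor median was 2.44-fold lower at percentile 5.35 and the AP2/ERF median 1.48-fold lower at 6.05. NAC lay above the middle 95% with a minimum of 200 reads and by distinct positions, and AP2/ERF below it with a minimum of 20. Reads of actin, GAPDH, 14-3-3, DEAD-box helicase and protein kinase families had medians at percentiles 33.2, 33.9, 53.3, 24.7 and 33.0.

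Tags at conserved miRNA sites started mostly 1 nt downstream of the base opposite nucleotide 10, the highest offset in 9 of 12 families. Besides miR171, described below, miR858 and miR156 differed. The miR858 family was highest at the predicted base, with 436 summed reads there and 9 at the next base. The miR156 family was highest 2 nt downstream, with 1223 reads there and 211 at 1 nt downstream. Chance matches of the miRNA sequences are argued against, since shuffled sets gave a mean of 0.35 supported sites against 27 before shared tags were counted once. Mulberry miRNA forms that start at another base than the sequences used stay open, since listed positions differed from the predicted base at some sites. For miR166f and miR319c the listed position was the peak, 1 nt past the predicted base. For miR160b, miR164a, miR171a and miR408c it was the predicted base, with the peak 1 nt further. The 1 family that peaked upstream did so at miR171 base 1254, 1 nt downstream of the listed miR171d position, 1253. The bounds of the test of such forms were set with the offsets in view, and forms with a further base at the 5′ end would also give the next base. A shift of 1 nt in how tags were trimmed or placed may account for the pattern, but 75% of families at that base lies exactly at the bound set for it, and with either other version of the search, neither of which holds miR166, the share was 72.7%, so the shift cannot be told apart from other sources. No biological explanation was tested.

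The 11 motif families outside the middle 95% of random lists may reflect an effect of drought, which 1 library per condition cannot separate from a difference between libraries. A pile-up of copies at 1 position of each transcript is argued against, since without the highest position 11 of the 11 kept their direction with at least 75% of their median log2 ratio. Copies spread over several positions are not addressed by that test. By distinct positions the median log2 ratio of histone H2A went from -2.20 to -0.37 and of pectinesterase from -1.21 to -0.46, while that of PP2C went from 0.41 to 0.59. Distinct positions are bounded by transcript length, so these values do not decide it. Reads shared between near-identical family members stay open. With single-match tags only, 9 of the 11 kept their direction with at least 75% of their median log2 ratio, between the bounds set for that test.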
